A study of Penicillium oxalicum with 15 samples.

How the data were processed

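The series holds RNA sequencing of mycelium from solid-state cultures of Penicillium oxalicum, 15 libraries in 5 groups of 3. Per the labels' protocols, strains grew without shaking at 28 °C for 5 days on 10 g of carbon source with 20 mL of a mineral salt solution, the carbon source having been dried at 50 °C and milled to 40 mesh. RNA was extracted with TRIzol, and complementary DNA libraries of 100 bp were sequenced on an Illumina HiSeq system, per the labels' protocols. Groups and replicate numbers came from the sample titles, with strain and carbon source checked against the other labels. No column of per-sample values was left out.

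Each deposited file lists, for 1 library, a gene identifier, an expected count and an FPKM value, per the file headers. The expected counts are estimated read counts per gene as the authors deposited them, which need not be whole numbers, and no scaling is stated. The FPKM values (fragments scaled by gene length and by sequencing depth) were computed by the authors from those estimates, and a gene at 0 is not listed in the deposited files. BWA 0.7.10-r789, Bowtie2 2.1.0, RSEM 1.2.12 and DESeq2 are named in the submitters' processing notes, without roles, order or a DESeq2 version. The genome build and annotation are not given in the sources used here.

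Estimated counts can split reads between genes, and the share of listed counts that were not whole was 0.17 to 0.31% in the 9 EU2101 libraries and 13.37 to 14.18% in the 6 MuKu70 and MuPOX03016 libraries. The ratio of count to FPKM gives each gene's effective length up to a factor per library. For 7011 genes with a count of at least 20 and an FPKM of at least 5, this length differed between the EU2101 and mutant libraries by a common shift of -71 bp. With a tolerance of 20 bp around that shift, 4995 genes had the same length in both apart from the shift and 2016 (28.8%) did not, of which 1984 were longer in the mutant libraries. These lengths stand for the gene model behind the values, and only comparisons within the EU2101 libraries or within the mutant libraries are free of that difference between them. Of the single lengths, 95% lay within 9.3 bp of the gene's median in EU2101 and within 125.2 bp in the mutant libraries. Some lengths thus varied among the mutant libraries by more than the tolerance, which makes the division of genes less sure. Across genes, EU2101 libraries and mutant libraries correlated at r of 0.579 to 0.708 over 8420 genes.

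The table of gene names at hand, of 9964 genes of strain HP7-1, matched 0 of the 9512 identifiers in the files. Genes are therefore given by identifier, and the gene lists that needed product names, such as cellulases, xylanases, sugar transporters and transcription factors, could not be formed, nor could counts of transcription factors be made. The fallback list of 13 identifiers was fixed before the data were examined. It was written from memory of published quantitative PCR panels, so that its members' functions rest on recall. The rule for named genes was fixed at the same time: POX03016, the 2 called identifiers with the largest rise and the 2 with the largest fall whose mean FPKM was at least 10 in the higher group and whose groups did not overlap, and up to 3 called members of the list of 13 with the largest change. Identifiers outside this rule that are named in the closing section were chosen after their values were seen.

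Expected counts were rounded to whole numbers and tested with edgeR 4.0.16 in R 4.3.3 (TMM scaling, filterByExpr with a minimum count of 10, quasi-likelihood F-test, Benjamini-Hochberg adjustment over the tested genes, threshold 0.05). All adjusted p-values of single genes come from this test unless another tool is named. The standard errors are the log2 fold change divided by the square root of the F statistic. The design written beforehand assumed FPKM files and limma on log2(FPKM + 1), with edgeR if counts were present, so the FPKM test became an alternative. The 3 comparisons between carbon sources were fitted together over the 9 EU2101 libraries, and the 2 comparisons between strains each over their own 6 libraries. The 13 identifiers were tested as a set with camera of limma 3.58.1 at a preset correlation of 0.01, adjusted over the 5 comparisons, and again with an estimated correlation, which gave no adjusted p under 0.05 in any of them. A fold against a group without counts was computed against a floor of 3 counts per library and is a lower bound. Where a group held 1 to 3 counts in all, the ratio has an exact 95% Poisson interval, and such intervals and floors cover counting error only. Genes are not independent replicates in correlations across genes.

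Replicates were compared before they were averaged, and no pair agreed within sampling noise (chi-square per degree of freedom between 8.0 and 56.5 over genes with at least 20 counts). Whether replicate numbers pair the samples was checked from the deviations of each library from its group mean. Same-numbered libraries deviated together with r of 0.57, 0.59 and 0.43 in WB plus AV against WB. In WR against WB plus AV they did so with r of 0.32, 0.43 and 0.23. All lay above the limit of 0.1 set beforehand, so the numbers were taken to pair these samples, which the labels do not state. With 3 libraries per group few matchings are possible, so such agreement could also arise by chance. In the other 3 comparisons at least 1 pair was under 0.1.

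The test was tried on simulated counts with 100 genes changed 2-fold and 100 changed 4-fold. It recovered 13% and 88% of these for WB plus AV against WB, 35% and 89% for WR against WB and 15% and 84% for WR against WB plus AV (8079 genes each), 70% and 94% for MuPOX03016 against MuKu70 (7931 genes) and 74% and 96% for MuKu70 against EU2101 (8287 genes). Many changes of 2-fold would thus be missed in the comparisons of carbon sources, where the biological coefficient of variation was 0.276, against 0.176 and 0.164 in the comparisons of strains.

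Alternatives fixed before the data were examined were other pseudocounts, filters on low values, TPM, quantile and median-ratio scaling, fits without a variance trend or with array weights, other sets of libraries in the fit, a replicate block, a 2-fold minimum, DESeq2 1.42.0 and its size factors, and leaving out each library in turn. Chosen after the data were seen were limma on log2(FPKM + 1), genes with whole counts only, genes with the same gene model only, the block without WB replicate 1, and the block for the overlaps. Tables and figures were made with python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.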

Results

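The series measured gene expression in mycelium of Penicillium oxalicum, a filamentous ascomycete fungus that secretes enzymes which break down plant cell walls. The cultures were solid-state fermentations, in which a fungus grows on moist solid particles without free liquid. RNA sequencing gave 15 libraries in 5 groups of 3. Strain EU2101 was grown on carbon source WB, on WB plus AV and on WR, and the strains MuKu70 and MuPOX03016 were grown on WR. The labels do not spell out these carbon source abbreviations, and they write AV in the titles but WA in the growth field, and WR in the growth field but WB_RS in the titles of the EU2101 libraries. Ku70 is a protein of DNA end joining, and fungal strains without it are common hosts for gene deletion, while POX03016 is a gene identifier of this species. The labels do not say how either mutant was made or whether replicates came from separate cultures. The p-values therefore weigh differences only against the spread between these samples, which may be technical.

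The deposited estimated counts summed to 2417284, 1782848 and 2265863 for replicates 1, 2 and 3 of EU2101 on WB, to 3152409, 1863613 and 2729955 on WB plus AV, and to 3414915, 3394496 and 3372763 on WR. The mutants were sequenced more deeply, with 7270189, 7335888 and 6753528 for MuKu70 and 6609605, 7056043 and 7138801 for MuPOX03016. Each library listed between 8574 and 8997 genes. Replicates of a group correlated at r of 0.972 to 0.984 on WR in EU2101, 0.976 to 0.985 in MuKu70, 0.976 to 0.984 in MuPOX03016 and 0.941 to 0.962 on WB plus AV, across genes on the log2 scale. Within WB, replicates 2 and 3 correlated at 0.97, while replicate 1 reached 0.905 and 0.91 with them and 0.959 with replicate 1 of WB plus AV. Genes are named by identifier alone, because none of the 9512 identifiers in the files could be paired with a gene name.

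**Figure D1:**
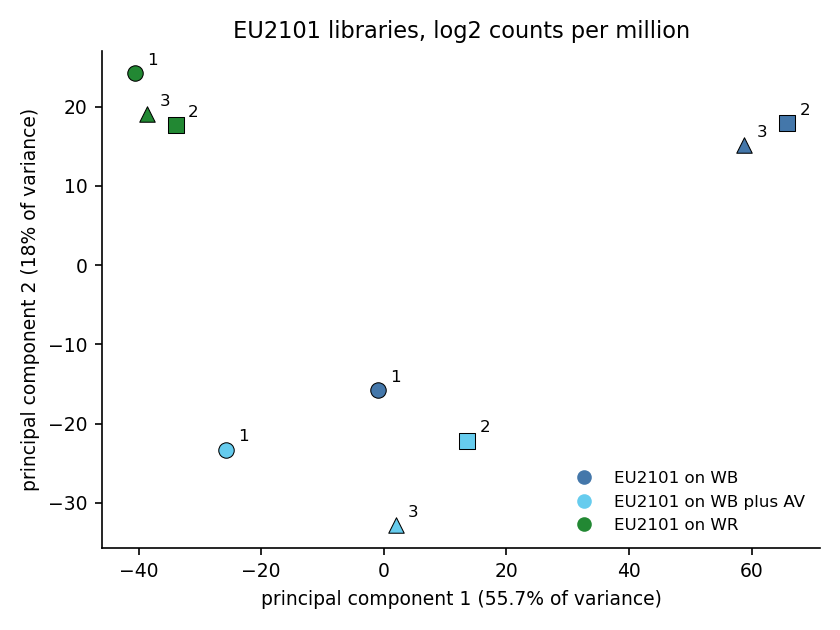
Principal components of the 9 EU2101 libraries, computed on log2 CPM; the axes give the share of variance, and each point is a library marked with its replicate number. The 3 WR libraries lie together between -40.58 and -33.95 on component 1, WB replicates 2 and 3 lie at 65.77 and 58.69, and WB replicate 1 lies at -1.02, among the WB plus AV libraries.

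POX03016 was read in every library and was lowest in the mutant that carries its name. It averaged 18.8 ± 1.0 FPKM (SD, n = 3) in MuPOX03016 and 105.1 ± 29.4 FPKM in MuKu70, so the mutant kept 17.9% of the MuKu70 level. The level fell by 2.33 on the log2 scale (SE 0.19, adjusted p = 0.0012 in edgeR), more than the spread between replicates. All 3 mutant libraries lay below all 3 MuKu70 libraries, and the exact 2-sided permutation test gave p = 0.1, the smallest value that 3 against 3 allows. The reads that remain, 275 to 319 counts per mutant library, cannot be placed within the gene from these files.

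In EU2101 the same gene stood at 293.9 ± 177.8 FPKM on WB, 256.2 ± 171.6 on WB plus AV and 138.2 ± 89.7 on WR. Replicate 2 had the highest POX03016 value in each of the 5 groups, at 499.21, 444.85 and 240.97 FPKM in the EU2101 groups. No EU2101 comparison passed the threshold without a block, with adjusted p = 0.875 for WB plus AV against WB, 0.256 for WR against WB and 0.512 for WR against WB plus AV in edgeR. With the replicate number as a block, POX03016 was lower on WR than on WB plus AV by a log2 fold change of -0.80 (adjusted p = 0.0329 in edgeR).

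**Figure D2:**
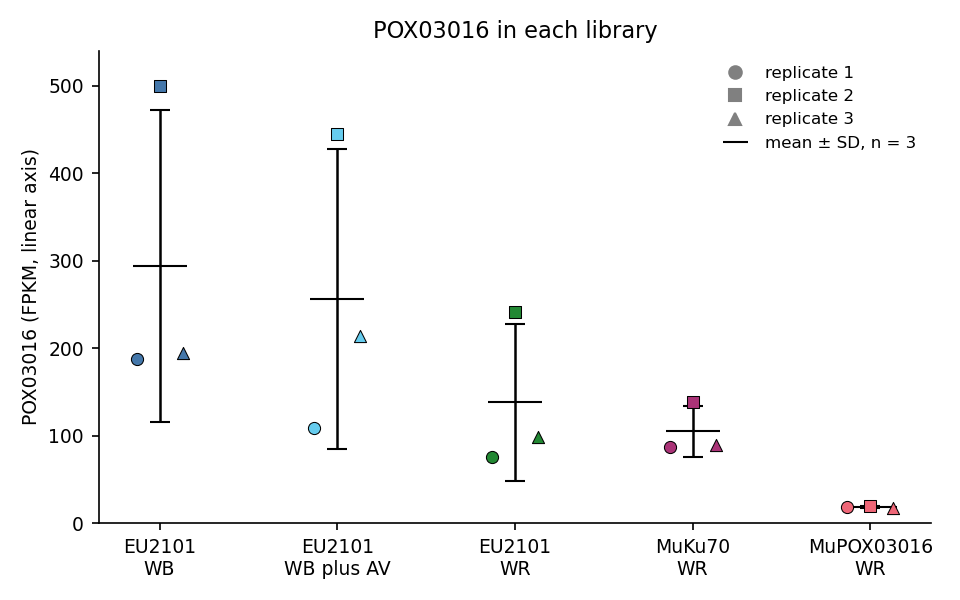
FPKM of POX03016 in each of the 15 libraries on a linear axis that starts at 0; points are libraries, horizontal marks the group mean and bars 1 SD (n = 3). The 3 MuPOX03016 libraries lie between 17.9 and 19.93 FPKM and the 3 MuKu70 libraries between 87.37 and 138.97. The gene model of POX03016 is not the same in EU2101 and mutant libraries, so its FPKM is comparable only within each of these.

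The title of the series asks how expression changes with the inducing carbon source. Adding AV to WB changed 95 of 8079 tested genes, 55 higher and 40 lower than on WB alone. POX09299 had no count in any WB library and reached 83.6 ± 31.1 FPKM (SD, n = 3) on WB plus AV, at least 9.28-fold higher against a floor of 3 counts per library (adjusted p = 0.0198). POX05007 rose from 7.49 ± 5.58 to 342.1 ± 31.7 FPKM, a log2 fold change of 5.51 (SE 0.43, adjusted p = 0.00123). POX00805 fell from 338.6 ± 42.0 to 16.8 ± 17.2 FPKM and POX03547 from 466.1 ± 321.2 to 28.7 ± 16.8 FPKM, with log2 fold changes of -4.42 (SE 0.68, adjusted p = 0.0229) and -4.13 (SE 0.79, adjusted p = 0.0404).

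A set of 13 identifiers, recalled before the data were examined from published quantitative PCR panels of plant-biomass-degrading enzyme genes of this species, was described as a group, and the function of its members was not checked here. In WB plus AV against WB, 2 of the 13 rose and none fell. POX04786 rose from 2854 ± 1171 to 10900 ± 2799 FPKM and POX01896 from 603.6 ± 202.5 to 2181 ± 374 FPKM, with log2 fold changes of 1.94 (SE 0.38, adjusted p = 0.0433) and 1.84 (SE 0.30, adjusted p = 0.0256). Adjusted over the list alone, 10 members rose and none fell. The median log2 fold change of the set was 1.62, or 3.06-fold, and camera gave adjusted p = 1.28e-10 against all other genes, but adjusted p = 0.102 with an estimated correlation. The 13 identifiers took 1.81 ± 0.43% of the FPKM sum on WB and 5.31 ± 0.93% on WB plus AV (SD, n = 3).

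The libraries with the same number deviated together in this comparison, and the paired fit with the replicate number as a block called 510 genes, 238 higher and 272 lower, with 10 of the 13 set members higher. WB replicate 1 stood apart from its group across all genes, which bears on each comparison with WB. The 13 identifiers took 2.29% of its FPKM sum, nearer to WB replicates 2 and 3 (1.68% and 1.45%) than to WB plus AV (6.15%, 5.49% and 4.31%). That share goes against an exchange with a WB plus AV library. The grouping with WB replicate 1 and WB plus AV replicate 2 exchanged called 632 genes, however, against 95 as labelled. That count cannot tell an exchange from a library that stands apart. Across all genes WB replicate 1 was nearer to WB plus AV, so an exchange stays undecided. Without WB replicate 1, 1769 genes passed and 10 set members rose, while with any other library of the 2 groups left out no set member passed, and 56, 7, 5, 4 and 4 genes passed without WB plus AV replicate 2, WB plus AV replicate 3, WB replicate 3, WB replicate 2 and WB plus AV replicate 1. Of the called genes named for this comparison POX05007 alone passed with each of the 6 libraries left out, and the others were lost without at least 1 library other than WB replicate 1 and with only the 2 groups in the fit. POX04786 was also lost in limma on log2(FPKM + 1) (adjusted p = 0.0608) and POX03547 after quantile normalization (adjusted p = 0.0567). The share of calls that were higher was 57.9% in edgeR, 46.1% (53 higher and 62 lower) in limma on log2(FPKM + 1) and 64.7% (55 higher and 30 lower) in limma after median-ratio centring of the same values.

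WR against WB was the largest contrast among the carbon sources by number of genes. It changed 1315 of 8079 tested genes, 700 higher and 615 lower on WR, and 935 of these by at least 2-fold. POX02284 rose from 0.85 ± 1.47 to 68.1 ± 7.66 FPKM (SD, n = 3; adjusted p = 0.000571), and since WB gave a single count against 157 on WR, the ratio of 102 had an exact 95% Poisson interval of 18 to 4050, for counting error only. POX09299, without counts on WB, reached 28.7 ± 15.1 FPKM on WR, at least 3.5-fold higher against the floor of 3 counts per library (adjusted p = 0.0079). POX00805 fell from 338.6 ± 42.0 to 5.17 ± 1.93 FPKM and POX07393 from 56.0 ± 33.8 to 0.847 ± 0.733 FPKM, with log2 fold changes of -6.03 (SE 0.74, adjusted p = 0.00127) and -6.03 (SE 1.24, adjusted p = 0.0113).

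Of the 13 recalled identifiers, 11 rose on WR against WB and none fell, and adjusted over the list alone 11 rose and 1, POX02740, fell. The largest rises were those of POX06783, from 212.4 ± 245.0 to 4271 ± 1007 FPKM, POX07535, from 160.7 ± 111.5 to 1843 ± 313 FPKM, and POX06147, from 297.3 ± 286.6 to 3077 ± 947 FPKM, with log2 fold changes of 4.49 (SE 0.78, adjusted p = 0.00577), 3.62 (SE 0.45, adjusted p = 0.00131) and 3.51 (SE 0.61, adjusted p = 0.0058). The members that did not pass over all genes were POX02740, at a log2 fold change of -1.34 (adjusted p = 0.0856), and POX06835, at -0.77 (adjusted p = 0.248). The set median was 1.94, or 3.84-fold, with camera adjusted p = 9.4e-10 and adjusted p = 0.102 with an estimated correlation. On WR the set took 7.04 ± 1.38% of the FPKM sum, and 11 of its members were among the 100 genes with the highest mean FPKM, against 6 on WB.

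Without WB replicate 1, 2962 genes differed between WR and WB, and POX02740 (-1.67, adjusted p = 0.0128) and POX06835 (-1.13, adjusted p = 0.0153) then fell while 11 members rose. Leaving out WB replicate 2, WB replicate 3, WR replicate 1, WR replicate 2 or WR replicate 3 gave 606, 580, 548, 579 and 606 genes. Of the called genes named for this comparison, POX07393 was lost without WR replicate 1 (adjusted p = 0.0507), and the others passed with each library left out.

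**Figure D3:**
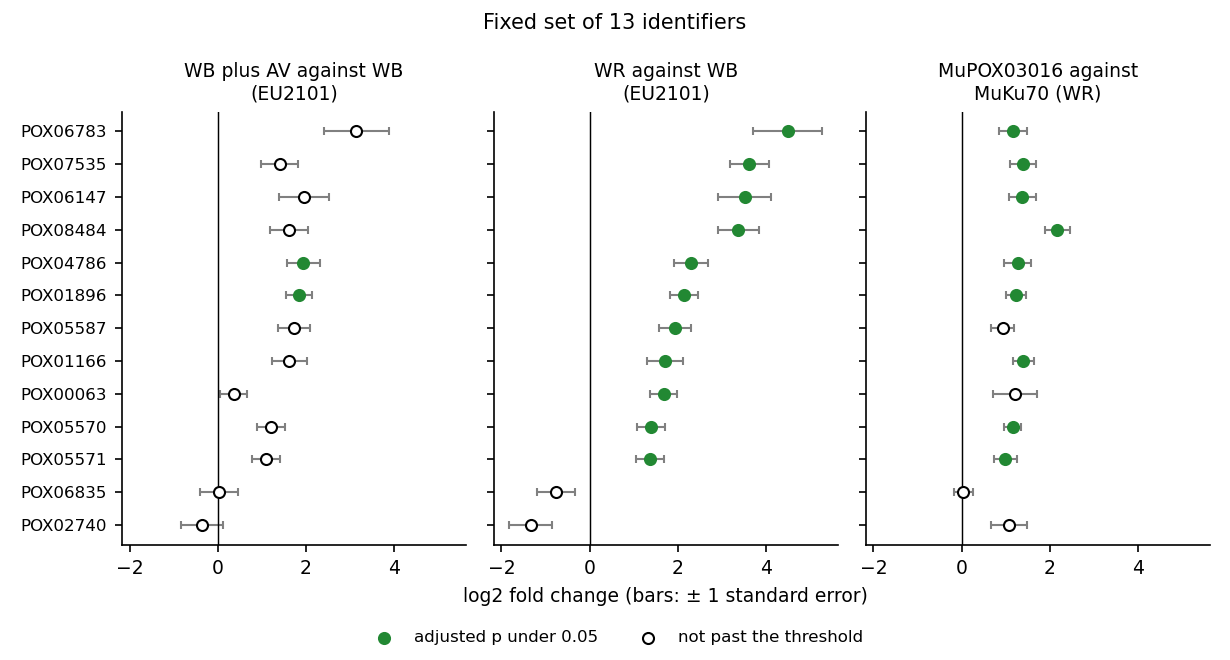
Log2 fold changes of the 13 recalled identifiers in 3 comparisons, with bars of 1 standard error; filled points had an adjusted p under 0.05 in edgeR over all tested genes. On WB plus AV against WB 2 members passed, on WR against WB 11 and in MuPOX03016 against MuKu70 9, all of them higher.

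Between WR and WB plus AV, 411 of 8079 genes differed, 262 higher and 149 lower on WR. POX02284 and POX07675 had the largest rises, to 68.1 ± 7.66 and 15.2 ± 4.06 FPKM (SD, n = 3) on WR, with 157 and 181 counts on WR against 1 and 2 on WB plus AV. The ratios were 125, with an exact 95% Poisson interval of 22.1 to 4960, and 71.9, with an interval of 19.6 to 598 (adjusted p = 0.00106 and 0.00194). POX07393 fell from 40.9 ± 44.8 to 0.847 ± 0.733 FPKM and POX05306 from 246.9 ± 296.5 to 6.47 ± 5.70 FPKM, with log2 fold changes of -5.49 (SE 1.25, adjusted p = 0.0332) and -5.14 (SE 1.07, adjusted p = 0.023).

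Of the recalled identifiers, 3 were higher on WR than on WB plus AV and none lower, both over all genes and adjusted over the list alone. These were POX07535 (414.8 ± 136.6 against 1843 ± 313 FPKM, log2 fold change 2.22, adjusted p = 0.0162), POX08484 (1760 ± 724 against 5609 ± 1701 FPKM, 1.74, adjusted p = 0.0458) and POX00063 (2479 ± 468 against 5948 ± 1282 FPKM, 1.32, adjusted p = 0.0358). The set median of 0.30 was small, camera gave adjusted p = 0.0106, and the call was lost with an estimated correlation (adjusted p = 0.309). Under quantile normalization the median was -0.08, of the opposite sign, with adjusted p = 0.325. The paired fit with a replicate block called 873 genes, 484 higher and 389 lower, and 5 of the 13 members. The share of calls that were higher was 63.7% in edgeR, 59.7% in limma on log2(FPKM + 1) and 53.3% (161 higher and 141 lower) in limma on TPM, and leaving out WB plus AV replicate 2, WB plus AV replicate 3, WR replicate 1, WR replicate 2 or WR replicate 3 gave 192, 160, 155, 183 and 179 genes. POX02284 and POX07675 passed with each library left out, POX05306 was lost with any 1 of the WR libraries left out, and each of POX07393 and the 3 set members was lost with any of at least 4 libraries left out in turn. POX08484 and POX00063 were also lost in limma on log2(FPKM + 1) (adjusted p = 0.0791 and 0.0598) and in limma on TPM, after quantile normalization and after median-ratio centring, so that 1 set member, POX07535, was called in each of these fits. The set members called fell from 3 to 1 without WB plus AV replicate 1 or WR replicate 2 and to 0 with any other library of the 2 groups left out.

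**Figure D4:**
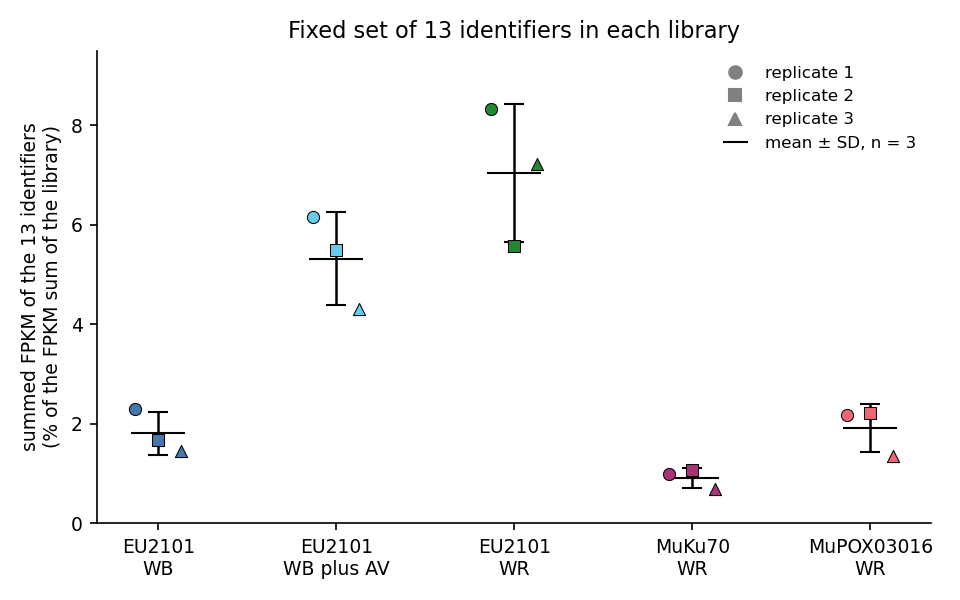
Summed FPKM of the 13 recalled identifiers as a percent of each library's FPKM sum, on an axis that starts at 0; points are libraries, horizontal marks the group mean and bars 1 SD (n = 3). The group means are 1.81% on WB, 5.31% on WB plus AV and 7.04% on WR in EU2101, 0.91% in MuKu70 and 1.92% in MuPOX03016. The gene model was the same in EU2101 and mutant libraries for 8 of the 13, so the shares are comparable only within EU2101 or within the mutants.

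The design text names a search for key transcription factors of cellulase and hemicellulase expression, and MuPOX03016 against MuKu70 on WR is the comparison of the series that bears on POX03016. In the mutant 1456 of 7931 tested genes differed, 857 higher and 599 lower, of which 284 and 253 changed by at least 2-fold. Of the 13 recalled identifiers 9 rose and none fell, and adjusted over the list alone 12 rose. POX08484 rose from 231.7 ± 49.9 to 953.1 ± 327.9 FPKM (SD, n = 3), POX01166 from 854.3 ± 139.9 to 2045 ± 484 FPKM and POX07535 from 903.9 ± 268.6 to 2175 ± 514 FPKM, with log2 fold changes of 2.17 (SE 0.29, adjusted p = 0.00385), 1.40 (SE 0.23, adjusted p = 0.00791) and 1.39 (SE 0.29, adjusted p = 0.0175). POX06835 was the member with the smallest change, 0.04 (SE 0.21, adjusted p = 0.917).

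The set median in the mutant was 1.21, or 2.32-fold, with camera adjusted p = 6.3e-07 and adjusted p = 0.261 with an estimated correlation. The set took 0.91 ± 0.21% of the FPKM sum in MuKu70 and 1.92 ± 0.48% in MuPOX03016. Under scaling by library totals, in limma on log2(FPKM + 1), the median of all genes lay at -0.13, the set median at 1.04 and 7 members were called. That scaling turned the balance of the calls, with 525 higher and 1002 lower (34.4% higher, against 58.9% in edgeR and 56% after median-ratio centring of the same FPKM values). Without MuKu70 replicate 1, MuPOX03016 replicate 1 or MuKu70 replicate 3, the members called fell from 9 to 3, 4 and 5, and without MuKu70 replicate 2 there were 6.

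The identifiers that the rule for named genes gave as the largest rises and falls in the mutant had fractional counts, so that reads may have been divided between genes and their values are uncertain. POX07524 had no count in MuKu70 and 17.7 ± 12.2 FPKM in the mutant, at least 117-fold higher against 3 counts per library (adjusted p = 0.00624), and POX00185 stood at 1.18 ± 2.04 and 16.4 ± 2.59 FPKM (log2 fold change 3.92, SE 0.96, adjusted p = 0.0311). POX02453 and POX08991 had no count in the mutant and 19.1 ± 9.54 and 11.99 ± 12.3 FPKM in MuKu70, at least 90.4-fold and 29.8-fold lower (adjusted p = 0.00468 and 0.031). With POX02454 the summed counts of POX02453 were 260 ± 24.8 CPM (counts scaled by the library total) in MuKu70 and 137 ± 7.64 CPM in the mutant, a log2 ratio of -0.92, while with POX08992 those of POX08991 were 210 ± 21.9 and 180 ± 2.52 CPM, a log2 ratio of -0.22. Over the genes with whole counts in all 6 libraries, an alternative chosen after the fractions were seen, 1228 genes differed, 736 higher and 492 lower. Leaving out MuKu70 replicate 1 gave 542 genes and leaving out MuPOX03016 replicate 3 gave 817. POX00185 was lost with any library other than MuKu70 replicate 2 left out, POX08991 without MuKu70 replicate 1 or MuPOX03016 replicate 1 or 3, and POX07535 without replicate 1 of either strain. With all libraries kept, POX00185 was lost in the DESeq2 test (adjusted p = 0.231) and POX08991 in limma on log2(FPKM + 5) (adjusted p = 0.0647).

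MuKu70 against EU2101 on WR describes the background between the strains. Of 8287 tested genes 5204 differed, 2606 higher and 2598 lower in MuKu70. Of the 13 recalled identifiers 12 were lower in MuKu70 and 1, POX06835, was higher, with the same numbers adjusted over the list alone. POX08484 stood at 231.7 ± 49.9 FPKM in MuKu70 and 5609 ± 1701 in EU2101 (SD, n = 3), POX05587 at 465.0 ± 69.1 and 7646 ± 1195, and POX04786 at 845.8 ± 172.5 and 13570 ± 2002, with log2 fold changes of -4.67 (SE 0.31, adjusted p = 7.15e-06), -4.06 (SE 0.25, adjusted p = 4.29e-06) and -4.04 (SE 0.28, adjusted p = 8.28e-06). The set median was -2.62, with camera adjusted p = 9.45e-06 and adjusted p = 0.261 with an estimated correlation.

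Some genes had counts in only 1 of these groups. A gene without counts has no effective length. A gene absent from the gene models behind 1 group therefore cannot be told apart from one not expressed there. POX02494 and POX00073 had no count in EU2101 on WR and 177.7 ± 19.5 and 724.9 ± 79.0 FPKM in MuKu70, at least 1300-fold and 938-fold higher against 3 counts per library (adjusted p = 1.02e-06 and 9.25e-07). POX08596 and POX03989 had no count in MuKu70 and 139.1 ± 15.6 and 36.7 ± 4.77 FPKM in EU2101, at least 762-fold and 540-fold lower (adjusted p = 6.49e-07 and 9.69e-07). POX03016 did not differ past the threshold, with a log2 fold change of 0.42 (SE 0.40, adjusted p = 0.39), but passed without EU2101 WR replicate 2 (1.03, adjusted p = 0.0067). Its sign differed between the kinds of value, from -0.25 to -0.13 in the limma fits on FPKM or TPM, whatever the scaling, and above 0 in each test on counts. POX03016 was not among the genes with the same gene model in EU2101 and mutant libraries, and FPKM divides by gene length. MuKu70 replicate 1 had 87.37 FPKM at 199 CPM, and EU2101 WR replicate 1 had 75.46 FPKM at 100.4 CPM. The reads counted for a gene depend on its gene model too. Neither the FPKM values nor the counts of POX03016 are therefore on one scale across EU2101 and the mutants. The median of all genes in this comparison lay at -0.006 in edgeR, at -0.095 in limma on log2(FPKM + 1) and at 0.127 in limma after quantile normalization of the same values, and the calls were 50.1%, 40.3% and 57% higher in that order. Every EU2101 library differs from every mutant library also in depth. The effective gene lengths behind the values differ by a common shift of -71 bp and, for 2016 of 7011 genes that could be compared, by other amounts. Of 4995 genes with the same length apart from that shift 2635 differed (52.8%), as did all 8 such set members, each lower in MuKu70. Length differences other than the shift thus do not account for all of the difference, while a batch of libraries cannot be told apart from the strain.

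The overlap of the calls was counted for genes tested in both of a pair of comparisons. WB plus AV and WR, each against WB, shared 35 genes that rose and 29 that fell and none that moved in opposite directions, where independent lists of these sizes would share 4.8 and 3.0. Both use the same WB libraries. At an unadjusted p under 0.05 lists of 1448 and 2610 genes shared 930 of the same direction and 25 of opposite directions, where independent lists would share 233.7 of the same direction. In 100 simulated sets without any effect, lists of a median of 386 and 388.5 genes shared a median of 91 and at most 112 of the same direction, and since these lists are shorter, the 91 is no bound on what shared controls add to the 930. The 3 WB libraries are too few to be split, so part of the excess may come from the shared controls. With a replicate block 379 genes were shared in the same direction. Without WB replicate 1 there were 1446, and without WB replicate 2, WB replicate 3 or WB plus AV replicates 1, 2 and 3 there were 1, 3, 3, 35 and 6.

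Genes that moved with WR against WB in EU2101 were set against those that moved in the mutant, with no library in common. Of 7633 genes tested in both, 96 were higher in both and 39 lower in both, where independent lists give 68.2 and 41.8. A further 116 genes were lower in MuPOX03016 and higher on WR, against 47.0 for independent lists, and 85 were higher in MuPOX03016 and lower on WR, against 60.7. With WB plus AV against WB the mutant shared 14 genes that were higher in both and 3 that were lower in both, against 5.6 and 2.7, and 11 moved in opposite directions. With the replicate block in both fits 126 genes were shared in the same direction. The same-direction overlap of 135 with WR moved to 57 without MuKu70 replicate 1, to 226, 79 and 80 without WB replicates 1, 2 and 3, and to 73 and 80 without WR replicates 1 and 3. The 17 shared with WB plus AV moved to 7 without MuKu70 replicate 1, to 11 without MuPOX03016 replicate 3, to 1, 9 and 1 without WB plus AV replicates 1, 2 and 3, and to 184, 0 and 1 without WB replicates 1, 2 and 3.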

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

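The limma test on log2(FPKM + 1), the restriction to whole counts or to the same gene model, the block without WB replicate 1 and the block for overlaps were chosen after the data were seen, and the other alternatives before. No named gene and no set test turned its direction past the threshold. The balance of higher and lower calls did turn under some alternatives. MuPOX03016 against MuKu70 gave 857 higher and 599 lower in edgeR, but 525 and 1002 in limma on log2(FPKM + 1). Of 836 alternative values for the 38 results on named genes, 744 kept their side of the threshold, 86 lost a call, 6 gained one and 0 were called in the opposite direction. The fall of POX03016 in MuPOX03016 passed in every alternative, between -2.47 and -2.11 on the log2 scale. The cause of the changes below was not tested, except that a 2-fold minimum and the same-gene-model restriction count fewer genes by construction and left-out libraries leave fewer samples.

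Counts of called genes moved by over 1.5 times as follows. Array weights gave 1588 genes for WB plus AV against WB, 3784 for WR against WB, 852 for WR against WB plus AV and 2528 for MuPOX03016 against MuKu70. All 15 libraries in 1 model gave 540, 2103, 663 and 712 in that order. DESeq2 gave 543 for WB plus AV against WB and 667 for WR against WB plus AV, and fitting only the 2 groups gave 3 and 733. A pseudocount of 0.1 gave 238 for WR against WB plus AV. A 2-fold minimum gave 537 for MuPOX03016 against MuKu70 and 2849 for MuKu70 against EU2101, where genes with the same gene model gave 2558.

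With the replicate number as a block, 510 genes passed for WB plus AV against WB, 873 for WR against WB plus AV and 2291 for WR against WB, and without WB replicate 1 the block gave 2335, 1926 and 3355. The block gave 1797 for MuPOX03016 against MuKu70 and 5104 for MuKu70 against EU2101. In WR against WB, MuPOX03016 against MuKu70 and MuKu70 against EU2101 the lowest pair correlations were 0.08, 0.03 and 0.03, under the limit of 0.1. The samples were not taken as paired there. Of 6 libraries 6, 5 and 5 correlated best with their own number. Since the numbers were taken to pair both WB and WR with WB plus AV, pairing of WR with WB stays open. With the block POX03016 passed on WR against WB (-1.10, adjusted p = 0.00408). It also passed in MuKu70 against EU2101, where its gene model differed (0.55, adjusted p = 0.0371). Among named genes and lists the block changed no other call than these and that of POX03016 on WR against WB plus AV.

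Leaving out 1 library moved the counts between 4 and 1769 for WB plus AV against WB, 548 and 2962 for WR against WB, 155 and 393 for WR against WB plus AV, 542 and 1270 for MuPOX03016 against MuKu70, and 4557 and 5018 for MuKu70 against EU2101.

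The set of 13 lost its call with an estimated correlation, at adjusted p = 0.102 for WB plus AV and for WR against WB, 0.309 for WR against WB plus AV and 0.261 for both comparisons of strains. WR against WB plus AV also lost it after quantile normalization (0.325). There fry, which asks whether the set changed at all and not whether it changed more than other genes, gave adjusted p = 0.0629. The overlap of WB plus AV with WR, 64 genes in the same direction, was 404 with all 15 libraries in 1 model, 379 with the block and 1 to 1446 with a library left out. In the same direction, the mutant and WR shared 76 genes with a 2-fold minimum and 290 with the block. With a library left out they shared 57 to 226. The mutant and WB plus AV shared 52 in the same direction with all 15 libraries, 126 with the block and 0 to 184 with a library left out. The mutant and WR moved 201 genes in opposite directions, 87 of them with a 2-fold minimum. Opposite directions were not counted under the other alternatives. Calls of transcription factors were not run, since no identifier could be paired with a product name. Depth limits genes with few counts, such as POX02284, whose ratio of 102 on WR against WB had an interval of 18 to 4050, and its effect on the counts of calls was not tested.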

Other observations

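The tests on neighbouring identifiers, fractional counts, gene models and batch were chosen only after the result was seen, as was the search for genes that follow POX03016, whose predictions were written before its own result.

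Genes that changed in MuPOX03016 against MuKu70 lay next to each other by identifier number more often than in permutations that treat genes as independent. Among 6636 genes with whole counts in all 6 libraries, 435 changed by at least 2-fold past the threshold, and 60 pairs of consecutive numbers changed in the same direction, 26 lower and 34 higher. In 10000 permutations of the changes over the genes the median was 11 pairs and the highest 26 (permutation p = 1e-04, the smallest they can give). There were 9 runs of at least 3 consecutive identifiers. The longest held 8 genes, POX09467 to POX09474, all lower, with a median log2 fold change of -2.12, and POX09335 to POX09340 held 6 lower genes with a median of -2.08. Among the higher runs, POX06599 to POX06603 held 5 genes with a median of 1.84 and POX09604 to POX09606 held 3 with a median of 3.63. The other comparisons were not counted in this way, so the values do not show that such runs are particular to the mutant. Whether consecutive numbers are adjacent in the genome was not checked here.

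Among genes called in MuPOX03016 against MuKu70, 14 of the 20 with a log2 change above 5 in size (70%) had fractional counts, against 16.3% of the 7931 tested genes and 19.2% of those called. Reads shared with the gene of the neighbouring number may account for such changes, since a split would give fractions that add to whole numbers, and with the number before, the number after or both, within 0.021 counts, 11 of the 14 (78.6%) added to whole numbers, below the 80% set for this test, while the highest of 50 other number distances gave 1. After that result the test was widened to up to 2 numbers on a side, which gave 14 of 14 against 1 at the other distances, and this wider count was chosen because the narrower one fell short. Of all 1295 tested genes with fractions 71.1% added to whole numbers in the narrow form and 86.4% in the wide form, so such sums were not particular to the genes with large changes. Whether a real change of 1 neighbour accompanies the shared reads stays open, as the sum of POX02453 and POX02454 went from 260 ± 24.8 CPM in MuKu70 to 137 ± 7.64 in the mutant (SD, n = 3), that of POX00185 and POX00184 from 191 ± 14.8 to 287 ± 23.7, that of POX07524 and POX07525 from 1030 ± 236 to 1230 ± 145 and that of POX08991 and POX08992 from 210 ± 21.9 to 180 ± 2.52.

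POX01829 fell from 128 ± 68 FPKM in MuKu70 to 1.67 ± 0.706 FPKM (SD, n = 3) in the mutant, a log2 fold change of -6.10. In EU2101 its count scaled by depth, like those of POX09306, also lower in the mutant, and POX08846, higher in the mutant, was highest in replicate 2 of each carbon source, where POX03016 was highest. POX07751, with 0, 1 and 1 counts in the mutant against 104, 231 and 14 in MuKu70, was highest in replicate 1 of each. POX02063, with 1, 0 and 0 counts in the mutant against 38, 36 and 26 in MuKu70, had at most 7 counts in any EU2101 library. The hypothesis that genes lower in the mutant follow the POX03016 level was tested within carbon sources over the 9 EU2101 libraries, leaving out 8 genes seen beforehand, and the difference it predicts was not found. The median correlation was -0.29 (Spearman -0.28) for 166 genes lower in the mutant and -0.10 (Spearman -0.05) for 195 higher, a difference of -0.19 with a 1-sided exact permutation p = 0.884 over 216 reorderings (Spearman difference -0.23, p = 0.917; smallest possible 0.00463), and without the 2 farthest libraries the medians were -0.17 and -0.19. The medians depend on the libraries, at 0.20 and 0.21 without replicate 1 of each carbon source, -0.49 and -0.20 without replicate 3 and -0.29 and -0.10 without replicate 2, and in each of these 3 the median of the genes lower in the mutant lay below that of the genes higher. With other genes in the place of POX03016, 32.8% of 3867 gave a smaller difference, so POX03016 did not stand apart, as a difference between replicates that moves many genes alike would also give, although the pattern that this was meant to explain was absent from the lists.

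The number of genes that differed between MuKu70 and EU2101 on WR, 5204, may partly come from the processing, since the EU2101 and mutant libraries differ in the effective length of many genes, which stands for the gene model. Genes with the same model in both were called in 52.8% of cases (2635 of 4995), those with another model in 78.1% (1575 of 2016), so gene models alone do not account for the count. A further 1276 genes had no effective length to compare, and 994 of them were called (77.9%). The median absolute log2 fold change was 0.42 with the same model, 0.89 with another and 2.59 without a length to compare. All 8 of the 13 recalled identifiers with the same model were lower in MuKu70, with a median log2 fold change of -3.33. A library or sequencing batch cannot be told apart from the strain, because 0 libraries of either strain lie among those of the other, and a difference between the strains stays open and untested. With at least 50 counts in each library of the other strains, 50 genes had none in the 6 mutant libraries and 7 had none in the 9 EU2101 libraries. Whether the gene models behind those libraries hold these genes cannot be seen from the values.

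Each comparison was set against the other splits of its 6 libraries into 3 and 3, which number 10 with the real one and are too few for a share under 0.05. WB plus AV against WB called 95 genes, and 2 of the 10 splits gave at least as many, the other being WB plus AV replicates 1 and 3 with WB replicate 1 against the rest, with 632 genes. That split is the exchange of WB replicate 1 with WB plus AV replicate 2, and it points to a structure of the samples. Of the 4 splits that part every pair of replicate numbers, the real one called the most here, and the highest of the others called 0. In WR against WB, WR against WB plus AV, MuPOX03016 against MuKu70 and MuKu70 against EU2101, 1 of 10 splits gave as many genes as the real groups (1315, 411, 1456 and 5204), and the highest of the others gave 0 in each.

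WB replicate 1 correlated across genes at 0.959, 0.949 and 0.946 with WB plus AV replicates 1, 2 and 3, and at 0.905 and 0.91 with WB replicates 2 and 3. The 13 recalled identifiers, fixed beforehand, took 2.29% of its FPKM sum, against 1.68% and 1.45% in WB replicates 2 and 3 and 6.15%, 5.49% and 4.31% on WB plus AV. POX09299 had no count in any WB library, but that gene was named because the groups as labelled differed, so it cannot test an exchange. The share goes against an exchange with a WB plus AV library. The grouping with WB replicate 1 and WB plus AV replicate 2 exchanged called 632 genes, however, against 95 as labelled. Without WB replicate 1 the labelled groups called 1769 genes, so the 632 cannot tell an exchange from a library that stands apart. The correlations and the share point different ways, so an exchange stays undecided, and why WB replicate 1 stood apart was not tested. POX03016 was highest in replicate 2 of all 5 groups, at 499.21, 444.85, 240.97, 138.97 and 19.93 FPKM on WB, WB plus AV, WR, in MuKu70 and in MuPOX03016.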
